A study of Komagataella pastoris with 15 samples.

How the data were processed

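Each of the 15 arrays was hybridised with Cy3-labelled cRNA from total RNA of 1 fermentor at 1 phase, per the labels. The deposited scanner files hold spot intensity on a linear scale, extracted with Agilent Feature Extraction; per the file headers the version was 10.7.3.1, whereas the submitters' processing notes name version 9.1. Per the file headers the processed intensity was background-subtracted within each array, and no normalization between arrays is recorded. The protocol lists several sampling times without tying them to phases, so no times are used.

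The authors also deposited a table of log2 values for 3915 of the 5039 probes (77.7%). How these were normalized is not given in the sources used here. Column medians lay between 12.6 and 12.7, and each column correlated with its own array's scanner values at r from 0.983 to 0.988, so the scale is log2 and the direction that of the signal, while the centring rule stays unknown. In this table the difference between scans, averaged over the first 4 phases, had an SD of 0.0053 against 0.71 in the scanner values for the same probes, so 0.754% of this mean was left, as subtracting a mean scan effect per probe would leave close to none. Within single phases the difference between scans still had an SD of 0.14 to 0.17 in the authors' values, against 0.71 to 0.80 in the scanner values of all tested tags. Each column correlated at r from 0.996 to 0.9996 with scanner values from which the scan difference had been removed while keeping the phases. The part of the scan difference shared by the phases was thus nearly absent from the authors' processed values, and no header or label used here records how. A fit to them without a scan term then counts 1 residual degree of freedom too many if the difference was removed by a fit, and a fit with that term was added after seeing the data.

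Starting from the scanner files, log2 of the processed signal was taken for all non-control spots, the 75th percentile of each array was subtracted, and the 3 spots of a probe were averaged without spots flagged as non-uniform or population outliers. Saturated spots were kept. This left 2.26% of probe values missing. Probes well above background (at least 2 of 3 spots) on all 3 arrays of at least 1 phase were tested, 5024 in all. The 5 phase means were fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes), with Benjamini-Hochberg adjustment over tags and a threshold of 0.05. The same test was made over the 5 phases with the moderated F statistic. Input was read with jsonlite 2.0.0, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Means ± SD average logarithmic growth arrays 2 and 3 first, whereas the fitted changes use all arrays.

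The procedure was tested on simulated data built from 3991 tags. At each size 66 or 67 tags were changed in 1 phase, far fewer than were called in the data. Each tag had 1 scan difference common to all phases, and the noise was normal and independent between arrays. The model with a scan block was thus the true one by construction, and the shares below hold for these settings only. For the first step, 11.9% of changes of 0.5 log2 units were recovered without a block and 62.7% with scan as a block, 55.2% and 94.0% of changes of 1 log2 unit, and 84.8% and 98.5% of changes of 2 log2 units, with 0 unchanged tags called without a block and 6 with it. For the fourth step 2 unchanged tags were called without a block and 13 with it.

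The labels give the same fermentor number at every phase, so the numbers pair the samples by culture. Deviations from the phase means of arrays with the same number correlated across probes, over the first 4 phases, at r from 0.941 to 0.954 for fermentor 1, from 0.795 to 0.917 for fermentor 2 and from 0.408 to 0.901 for fermentor 3. Fermentor 1 coincides with scan 1 in those phases, so the scan enters the pairing. Deviations from a phase mean cancel out over its arrays, so the scan also enters the r of fermentors 2 and 3. With the end of fermentation, where all arrays share scan 1, r ran from -0.051 to 0.052 for fermentor 1. It ran from 0.176 to 0.257 for fermentor 2 and from -0.314 to -0.196 for fermentor 3. How much of the pairing is due to the culture is not settled by these values. The main fit has no block, and the fermentor and the scan were fitted as blocks as alternatives.

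The rule for named genes, set before the data were examined, took the largest rises and falls among called genes with a description and no overlap between the arrays of both groups, called members of gene lists, and a fixed panel of genes. The files give locus tags without names or descriptions, and 0 of the 5039 tags matched the 5305 rows of the reference table for assembly ASM170810v1. The lists, the panel and the product transcript were therefore not analysed here. In their place the 2 largest rises and the 2 largest falls per comparison are named, among called tags with a value on all 6 arrays and no overlap between the groups (chance gives no overlap in 10% of tags). Tags picked as the largest called changes were likely to keep their call in refits of the same arrays. No sequence or position is given for the tags.

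Alternatives set before the data were examined were quantile normalization, median centring, normexp background correction with an offset of 50, the authors' processed values, other filters on dim probes, a trended prior, array weights, fits of 6 arrays only, the fermentor as a fixed or random block, the scan as a block, a threshold of 0.01, a minimum of 2-fold, and leaving out each array. Normexp was run on median in place of mean spot signals. Fits with scan as a random block, with both blocks, with near-identical arrays averaged, with outlier spots kept and within each scan were added after seeing the data.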

Results

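Transcript levels were measured at 5 stages of a fed-batch fermentation of the methylotrophic yeast Pichia pastoris (Komagataella pastoris in the labels) that produced recombinant human serum albumin (rhHSA). Total RNA from fermentors of 40 L, numbered 1 to 3, was hybridised to 15 Agilent arrays with a single dye, 3 arrays per phase. The phases were logarithmic growth, the end of glycerol feeding after 40 min of starvation, growth adapted to methanol, the peak of rhHSA expression, and the end of fermentation, for which the labels give 220 mg/L of rhHSA. Between 98.7% and 99.96% of the 5039 probes were well above background on each array of either scan, and at most 8 spots per array were saturated. The number of arrays limits the precision. The files name each probe by a locus tag alone, so results are given by tag, with at most 2 tags that rose and 2 that fell per comparison.

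The arrays came from 2 scans. Scan 1 held 7 arrays, namely fermentor 1 of the first 4 phases and all 3 arrays of the end of fermentation, and scan 2 held the other 8. Arrays of 1 phase on the same scan correlated across probes at r from 0.988 to 0.999, and arrays of 1 phase on different scans at r from 0.941 to 0.960 (probes are not independent replicates). The difference between scans had a standard deviation of 0.72 log2 units over probes, and limma called it for 3941 of 5024 tags. Each of the first 3 steps and the comparison of methanol with logarithmic growth had the same balance of scans in both groups. The difference between scans still enters their unblocked SEs. In every named result the SE was lower with scan as a block, for PAS_chr3_0023 at the first step 0.13 against 0.33. The last step lacked this balance, and its values with scan as a block stand beside the unblocked ones. Logarithmic growth arrays 2 and 3 differed by less than the noise between spots (1.94% of probes beyond it at p below 0.05, against 6.70% to 55.6% for the other pairs on 1 scan). They were counted as 1 sample in the means of that phase alone, so n = 2 there. The fits, with their SEs, p-values and counts, kept them as separate arrays. With them averaged and no scan block, 1853 tags were called at the first step against 2179. For methanol against logarithmic growth the count was 2410 against 2703. End of glycerol feeding arrays 2 and 3 (7.67%) and the 3 end of fermentation arrays (6.70% to 8.85%) had the next lowest shares beyond spot noise. These, with logarithmic growth arrays 2 and 3, are the near-identical arrays averaged in some refits. The SD at the end of fermentation may thus hold little spread between cultures, though n = 3 is given. In the first 4 phases the arrays span both scans, so the SDs there include the difference between scans. In logarithmic growth n = 2 means 1 value per scan, and its SD cannot part cultures from scans.

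**Figure D1:**
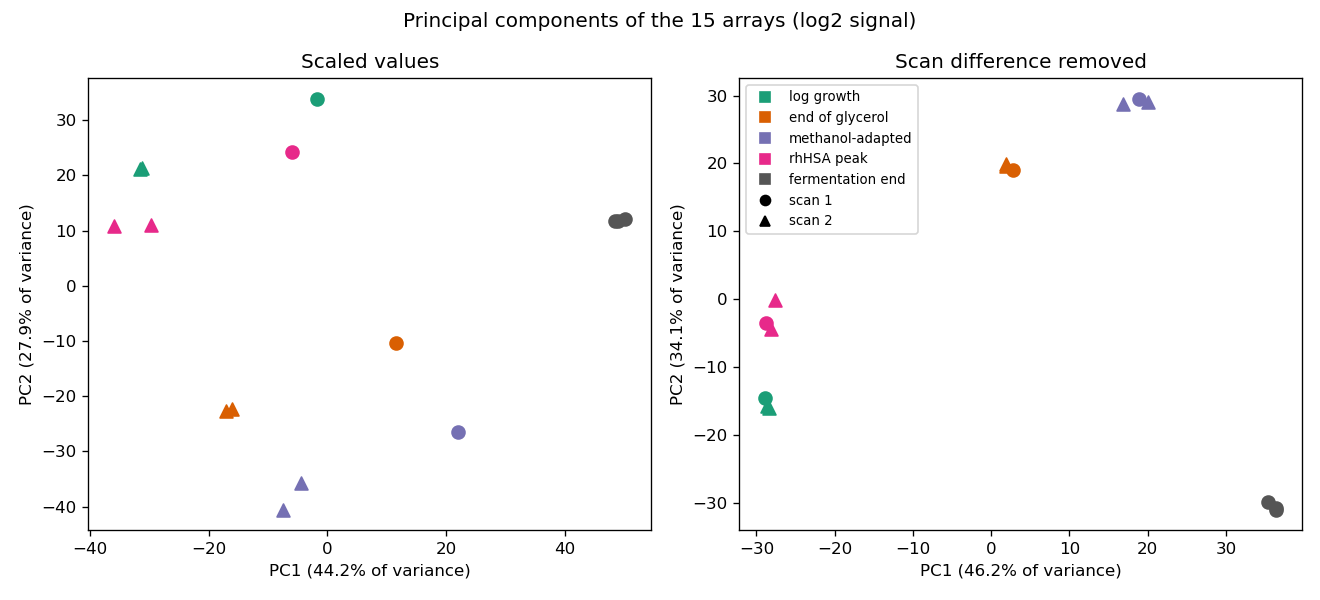
Principal components of the 15 arrays on log2 signal over 3991 tags with a value on every array, with scaled values on the left and with the difference between scans removed on the right; colours mark phases, circles scan 1 and triangles scan 2. Before removal PC1 and PC2 held 44.2% and 27.9% of the variance and arrays of 1 phase were parted by scan; after removal the arrays of each phase lay together, with rhHSA peak next to logarithmic growth on PC1.

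Most of the measured transcriptome differed among the phases. Of 5024 tags tested, 3905 differed among the 5 phases by the limma F-test, and 4827 did with scan as a block. Among consecutive steps the change from the end of glycerol feeding to methanol adaptation had the fewest calls (1427), here and in each alternative run on all 4 steps. The end of fermentation against the rhHSA peak had the most (2907), but this order did not hold with array weights (3762 against 4097 at the first step), with fermentor and scan both as blocks (3526 against 3734 at the third step) or with all near-identical arrays averaged and a scan block (3062 against 3410 at the third step).

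**Figure D2:**
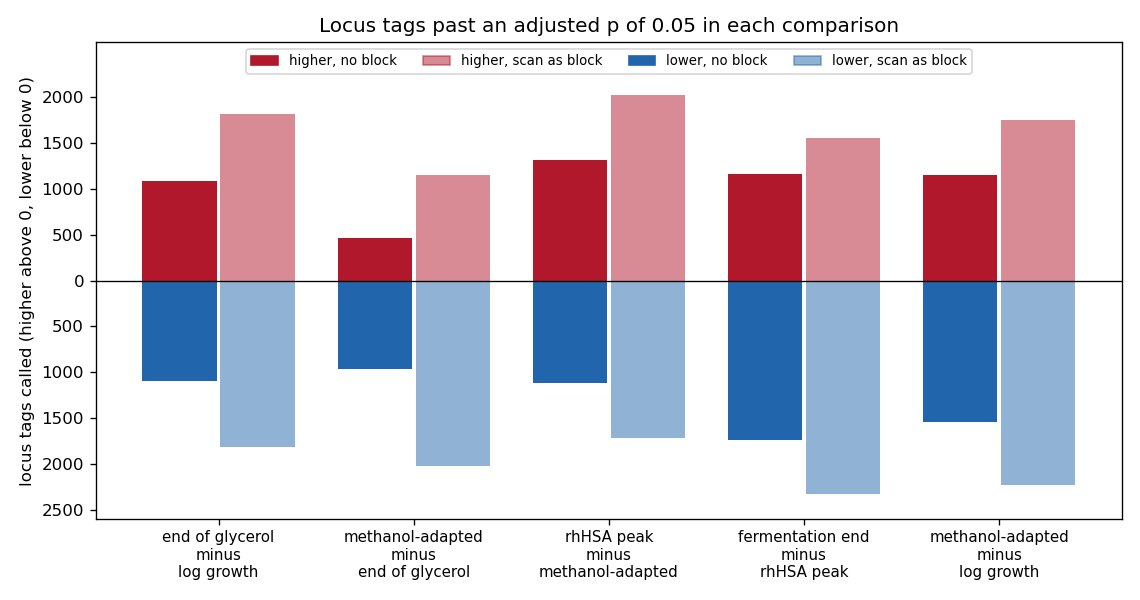
Number of locus tags past an adjusted p of 0.05 (limma) in each comparison, higher above the zero line and lower below it, without a block (dark bars) and with scan as a block (light bars). Unblocked counts ran from 1427 for methanol adaptation against the end of glycerol feeding to 2907 for the end of fermentation against the rhHSA peak, and every blocked count was higher.

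The first step asked what changed between growth on glycerol and the starved cells at the end of glycerol feeding. Rises and falls were nearly balanced, with 1082 tags higher and 1097 lower at the end of glycerol feeding, and 440 higher and 479 lower by at least 2-fold. The largest rise was that of PAS_chr3_0023, from -2.96 ± 0.49 (SD, n = 2) to 2.37 ± 0.39 (SD, n = 3) in log2 signal relative to the 75th percentile of the array. Its fitted change was 5.22 ± 0.33 (SE), which is 37.2-fold, with a limma adjusted p of 2.05e-07. PAS_chr4_0152 rose by 4.80 ± 0.60 (SE; limma adjusted p = 4.21e-05). PAS_chr2-1_0015 fell by 5.12 on the log2 scale, with an SE of 0.77 (limma adjusted p = 0.000187), and PAS_chr4_0369 fell by 4.01, with an SE of 0.096 (limma adjusted p = 1.07e-09). The fitted fall of PAS_chr2-1_0015 differed between scans, at -6.72 on scan 1 and -4.32 on scan 2. Its signal at the end of glycerol feeding was low, at -8.12 on scan 1 and at -6.20 and -6.13 on scan 2, though called well above background on all 3 arrays. At so low a signal the size of the fall is uncertain, and the values do not show that it truly differed between scans. With scan as a block 3637 tags were called, 1821 higher and 1816 lower. Over all tags the change on scan 1 correlated with that on scan 2 at r = 0.955, and 988 of 993 tags that changed at least 2-fold on scan 1 had the same direction on scan 2.

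The second step asked what changed from the end of glycerol feeding to full adaptation to methanol. Falls outnumbered rises, with 965 tags lower and 462 higher, and 253 lower and 106 higher by at least 2-fold. PAS_chr3_0448 rose from -4.20 ± 0.76 (SD, n = 3) to 1.25 ± 0.63 (SD, n = 3), a fitted change of 5.45 ± 0.47 (SE) or 43.6-fold (limma adjusted p = 6.04e-06). PAS_chr1-3_0041 rose by 3.49 ± 0.10 (SE; limma adjusted p = 1.18e-09). PAS_chr2-2_0393 fell by 2.71, with an SE of 0.19 (limma adjusted p = 1.23e-06), and PAS_chr1-3_0226 fell by 2.67, with an SE of 0.20 (limma adjusted p = 1.71e-06). The excess of falls depended on the scaling. It stayed with median centring, at 485 tags higher and 799 lower. With quantile normalization, which gives every array the same distribution, 597 tags were higher and 710 lower, and in the authors' processed values 1398 were higher and 1404 lower. The count was 3180 with scan as a block (1156 higher, 2024 lower), 2310 with fermentor as a replicate block and 497 when the fit held only the 6 arrays of these phases, and the change on scan 1 correlated with that on scan 2 at r = 0.925.

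The third step asked what changed from methanol adaptation to the arrays labelled as the peak of rhHSA expression. These arrays correlated best with logarithmic growth, and it is in doubt whether they hold the phase that their label names, so each value given here for the rhHSA peak, in the fourth step too, is that of the arrays so labelled. The step had 1321 tags higher and 1114 lower, and 705 higher and 495 lower by at least 2-fold. Which direction had more calls depended on the scaling. With median centring 1319 were higher and 1083 lower, with quantile normalization 1222 were higher and 1249 lower, and in the authors' processed values 1519 were higher and 1674 lower. PAS_chr1-1_0482 rose from -4.53 ± 0.45 (SD, n = 3) to -0.44 ± 0.14 (SD, n = 3), a fitted change of 4.09 ± 0.18 (SE) or 17.0-fold (limma adjusted p = 8.50e-09), and PAS_chr1-3_0134 rose by 3.89 ± 0.23 (SE; limma adjusted p = 1.71e-07). PAS_chr3_0448, the tag with the largest rise at methanol adaptation, fell by 4.88 with an SE of 0.47 (limma adjusted p = 3.28e-06), to -3.63 ± 0.68 (SD, n = 3). PAS_chr3_0023, the tag with the largest rise at the first step, fell by 4.55 with an SE of 0.33 (limma adjusted p = 3.22e-07). With scan as a block 3739 tags were called, 2025 higher and 1714 lower, and the change on scan 1 correlated with that on scan 2 at r = 0.975.

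**Figure D3:**
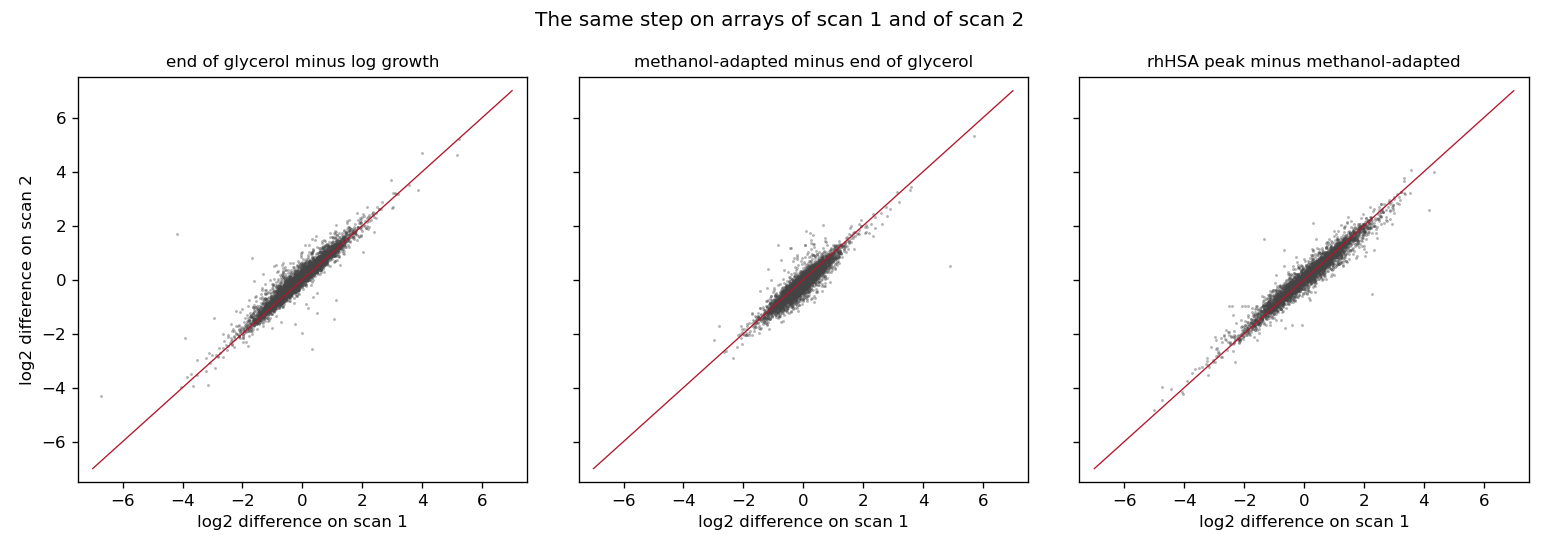
Log2 difference of each locus tag at the first 3 steps on the arrays of scan 1 (horizontal axis) and on those of scan 2 (vertical axis), with 1 point per tag and the line of equal change in red. Points lie along the line, with r of 0.955, 0.925 and 0.975 over tags with a value on every array used.

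The fourth step asked what changed from the peak of rhHSA expression to the end of fermentation. Falls outnumbered rises, with 1745 tags lower and 1162 higher at the end of fermentation, and 1067 lower and 661 higher by at least 2-fold. PAS_chr1-4_0042 rose from -4.20 ± 0.50 (SD, n = 3) to 1.28 ± 0.011 (SD, n = 3), a fitted change of 5.47 ± 0.42 (SE; limma adjusted p = 4.14e-07) that was 4.79 ± 0.16 (SE), or 27.7-fold, with scan as a block. PAS_chr1-1_0037 rose by 4.92 ± 0.76 (SE; limma adjusted p = 0.000195) and by 3.76 ± 0.52 with the block. Its signal at the rhHSA peak was low and uneven, at -4.90, -7.25 and -5.26 on arrays 1 to 3, so the size of its rise is uncertain. PAS_chr3_1145 fell by 5.26 with an SE of 0.65 (limma adjusted p = 2.37e-05) and changed by -4.15 with the block, and PAS_chr1-1_0036 fell by 5.08 with an SE of 0.19 (limma adjusted p = 1.22e-09) and changed by -4.88 with the block. All end of fermentation arrays were on scan 1, so the unblocked changes carry part of the difference between scans. With scan as a block 3888 tags were called (1558 higher, 2330 lower), including 2859 of the 2907 and each of these in the same direction. On scan 1 alone, where the peak had 1 array and so no spread of its own, the 4 named tags changed by 4.97, 4.02, -4.25 and -5.06, in the order given, and no test is drawn from it. The excess of falls depended on the scaling. It stayed with median centring, at 1078 tags higher and 1865 lower (597 and 1167 by at least 2-fold). With quantile normalization 1358 tags were higher and 1501 lower (781 and 823 by at least 2-fold), and in the authors' processed values 1649 were higher and 1642 lower (680 and 588).

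Growth on methanol was also set against logarithmic growth on glycerol, a comparison that shares its arrays with the first 2 steps. In methanol-adapted cells 1157 tags were higher and 1546 lower, and 584 were higher and 910 lower by at least 2-fold. The excess of falls depended on the scaling. It stayed with median centring, at 1230 higher and 1438 lower. With quantile normalization 1387 were higher and 1398 lower, and in the authors' processed values 1708 were higher and 1642 lower. PAS_chr3_0448 was higher by 5.01 ± 0.47 (SE) on the log2 scale, or 32.3-fold (limma adjusted p = 2.14e-06), and PAS_chr1-4_0597 by 4.93 ± 0.78 (SE; limma adjusted p = 0.000172). The signal of PAS_chr1-4_0597 in logarithmic growth was low, at -3.98 on scan 1 and at -6.35 and -6.32 on scan 2. Its change was 4.55 on scan 1 and 5.11 on scan 2, but at so low a signal the size is less certain. PAS_chr2-1_0015 was lower, at -4.69 ± 0.77 (SE; limma adjusted p = 0.000244), with -7.03 on scan 1 and -3.52 on scan 2, and PAS_chr1-4_0634 was lower, at -4.24 ± 0.45 (SE; limma adjusted p = 6.55e-06). The signal of PAS_chr2-1_0015 in methanol-adapted cells was low, at -8.4 on scan 1 and at -5.6 and -5.1 on scan 2. The size of its change is therefore uncertain. With scan as a block 3990 tags were called, 1757 higher and 2233 lower, and the difference on scan 1 correlated with that on scan 2 at r = 0.968.

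**Figure D4:**
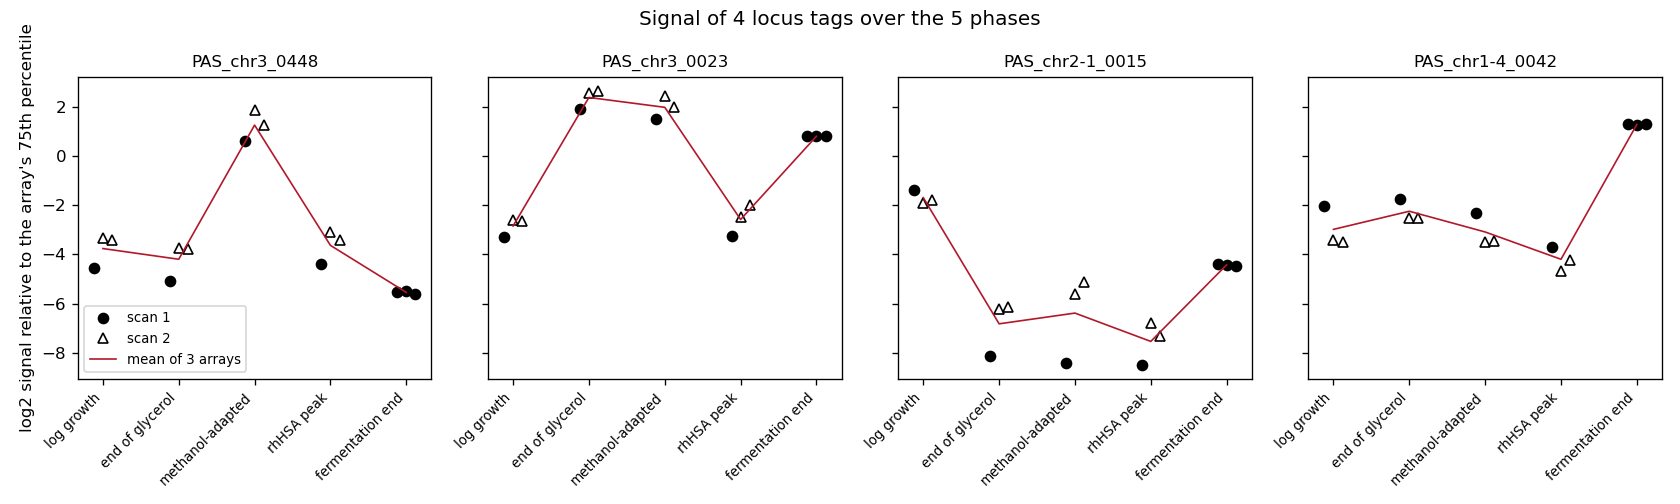
Log2 signal relative to the 75th percentile of each array for 4 of the named locus tags over the 5 phases, with filled circles for arrays of scan 1, open triangles for arrays of scan 2 and a red line through the means of the 3 arrays. PAS_chr3_0448 was highest in methanol-adapted cells at 1.25, PAS_chr3_0023 was at 2.37 at the end of glycerol feeding and at -2.58 at the rhHSA peak, PAS_chr2-1_0015 was highest in logarithmic growth and PAS_chr1-4_0042 was highest at the end of fermentation at 1.28.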

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

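The fits with both blocks, with scan as a random block, with averaged arrays, within 1 scan, and with a scan block plus another scaling or the authors' values were chosen after seeing the data. The 20 named results kept direction and call in all 550 result-refit pairs (up to 28 a result) without scan 1 alone. Counts mostly stayed within 1.5 times of 2179, 1427, 2435 and 2907 for the 4 steps, 2703 for methanol adaptation against logarithmic growth and 3905 over the phases. At the second step most refits other than leaving out 1 array went beyond this. The 3118 calls at the first step in the authors' values were of 3915 tags, a higher share than 2179 of 5024. For the first step the exceptions were 4097 with array weights, 3637 with a scan block, 3597 with scan as a random block, 3362 with logarithmic growth arrays 2 and 3 averaged and a scan block, 3639 and 3771 with median centring and quantile normalization plus a scan block, and 919 at 2-fold or more. For the second step they were 2802 in the authors' values and 2721 there with a scan block, 2365 with array weights, 497 with 6 arrays, 3180 with a scan block, 3091 with scan as a random block, 3102 and 2308 with logarithmic growth arrays 2 and 3 or all near-identical arrays averaged plus a scan block, 2156 on scan 2 alone, 3171 and 3249 with median centring and quantile normalization plus a scan block, 815 at the stricter threshold of 0.01 and 359 at 2-fold or more. For the third step they were 3739 with a scan block, 3689 with scan as a random block, 3690 with logarithmic growth arrays 2 and 3 averaged plus a scan block, 3747 and 3893 with median centring and quantile normalization plus a scan block, and 1200 at 2-fold or more. At 2-fold or more the fourth step gave 1728 and methanol against logarithmic growth 1494, and the latter 4115 with quantile normalization plus a scan block. With fermentor as a replicate block the steps gave 2986, 2310, 3173 and 3631 tags, methanol against logarithmic growth 3477 and the phases 4646, with 2366 for the second step as a random block; adding the scan to this pairing gave 3658, 3176, 3734 and 3526 for the 4 steps. Averaging logarithmic growth arrays 2 and 3 without a scan block gave 1853, 1319, 2354 and 2837 for the steps. Leaving out 1 array gave 1850 to 2194, 1003 to 1333, 2194 to 2314 and 2539 to 2926 for the steps, 2406 to 2705 for methanol against logarithmic growth and 3507 to 4095 over the phases. Quantile normalization moved the median change of all tags from -0.13 to -0.01 at the second step, from -0.18 to -0.04 at the fourth and from -0.11 to 0.03 for methanol against logarithmic growth, and so moved the split of higher and lower calls. Stricter thresholds lower a count by construction, and causes of the rest were not tested. A mean over probes (1 per tag) and the gene lists were not run. Nearly all probes were above background.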

Other observations

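Each phase also had tags that set it apart from all others. With scan as a block, 629 tags were higher and 1098 lower at the end of fermentation than in each of the other 4 phases, 126 and 302 of them by at least 2-fold. Methanol-adapted cells had 430 higher and 718 lower (44 and 63 by at least 2-fold), logarithmic growth 564 and 333 (37 and 0), and the end of glycerol feeding 379 and 174 (15 and 4). Arrays labelled rhHSA peak had 341 higher and 417 lower (1 and 26 by at least 2-fold). Without a block there were 414 higher and 759 lower for the end of fermentation (154 and 352 by at least 2-fold), 175 and 321 for methanol adaptation (37 and 65), 216 and 95 for logarithmic growth (39 and 0), 133 and 60 for the end of glycerol feeding (11 and 4) and 78 and 169 for the rhHSA peak (1 and 18).

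Weak shared change was seen between tags numbered 2 apart. The change of a tag on scan 1 was set against that of a tag with a higher number on scan 2, at 4 distances in 4 comparisons. At a distance of 2, r was 0.0621 at the first step, 0.0994 at the second, 0.0685 at the third and 0.0779 for methanol against logarithmic growth (adjusted p = 0.0032 each over 16 relations, from the smallest p that 1000 permutations within tag prefixes can give). At distances of 1 and 5 only the second step passed (r = 0.0859, adjusted p = 0.0032, and r = 0.0343, adjusted p = 0.0293, by permutation), and at a distance of 10 none did, with r from -0.0104 to 0.0179. Of 55 camera tests of tag prefixes over the 5 comparisons, 0 were called with a preset or an estimated correlation.

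Every test from here on was chosen after the results were seen, except the counts of other splits of the arrays, and so were those of tags with nearby numbers and of tag prefixes. In the first 4 phases fermentor 1 stood apart from fermentors 2 and 3, and by the same per-tag differences in each phase (r from 0.941 to 0.954 between phases). At the end of fermentation, where the 3 fermentors shared scan 1, fermentor 1 minus the others had an SD of 0.0999 log2 units against 0.72 for the earlier difference. The slope of the first on the second was -0.000931. This argues against a lasting difference of fermentor 1 only if these arrays came from separate cultures, which their near identity leaves in doubt. A difference between scans is consistent with both values and may account for the separation. No biological explanation that ends before the last phase was tested.

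Arrays labelled rhHSA peak lay nearer to logarithmic growth than to any other phase, with an RMS difference of 0.51 log2 units against 0.76 from the end of glycerol feeding and 0.95 from methanol adaptation, with scan as a block. The scan does not account for it, since within scans all 3 arrays correlated best with logarithmic growth, by a margin in r of at least 0.0271. Scaling does not either, because the RMS difference stayed at 0.677 of that from the next phase or less under quantile normalization and in the authors' values. Between them 1097 tags were called without a block and 2906 with scan as a block, which argues against repeats of 1 sample set. Whether the label names the phase is thus in doubt, since an exchange of phase labels cannot be told apart from a return of expression by these values and no named genes were used here to check it, and the biological change between phases stays open as a hypothesis that was not tested.

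Logarithmic growth arrays 2 and 3 differed beyond the spread of their spots at 1.94% of probes, below the nominal 5% of the test. The SD of their difference was 0.0825, below the 0.110 that their spots gave. The test may thus be conservative, and its true share under spot noise alone is not known. One RNA sample hybridised on both arrays is a candidate explanation, whereas the other pairs on 1 scan exceeded 5%. Fermentors that grew almost alike were not excluded. Averaging them gave 1853 calls at the first step without a block, against 2179.

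The differences of array 3 from array 2 at methanol adaptation and at the rhHSA peak correlated with each other at r = 0.819 across probes. They also correlated with the difference between scans, at r = 0.356 and 0.448. Array 2 was dimmer than array 3 in both phases (median signal 3433 against 7187, and 2919 against 5882). It also had more outlier spots (1870 against 280, and 3167 against 256). Array 3 minus array 2 had an SD over probes of 0.394 at methanol adaptation and 0.413 at the rhHSA peak. It was 0.0825 in logarithmic growth, 0.190 at the end of glycerol feeding and 0.119 at the end of fermentation. No difference of that size was thus seen in these other phases, but their near-identical arrays may not hold separate cultures. A difference of the cultures, lasting or not, cannot be told apart from a technical one here. Of the 10 ways to split the 6 arrays of each comparison, the real one called 2179, 1427, 2435, 2907 and 2703 tags and the highest other 0, 1, 2, 0 and 0; in each comparison 1 split reached the real count, and 10 splits are too few for a share under 0.05. Of 100 groupings of the 15 arrays over the 5 phases, 1, the real one, gave as many as 3905 tags, and the highest other gave 673. The other groupings moved arrays freely across fermentors and scans and could part near-identical arrays. Since arrays share fermentors and scans, they are not exchangeable, and this count does not exclude chance.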
